A study of Homo sapiens with 17 samples.

How the data were processed

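Total RNA was measured in 17 libraries of human hepatocytes, collected as cell pellets at day 10. The labels give the medium of each library, LGLI in 9 and NASH in 8. The authors deposited estimated counts per gene symbol for each library, and these are not scaled to a common depth. Per the submitters' processing notes, kallisto and the genome build GRCh38 were used. kallisto assigns reads to transcripts without full alignment and shares reads that fit several transcripts between them. Its version, the transcript annotation, the handling of strand and the step from transcripts to genes are not given in the sources used here. Only 0.208% to 1.27% of the nonzero values of a library are whole numbers, within a tolerance of 0.001. This can come from shared reads or from counts scaled from abundance, which the sources used here do not tell apart. If they were scaled, the values are not numbers of reads. Genes with near-identical copies have uncertain separate values, as do overlapping and antisense genes if strand was not used. The table holds 19578 symbols, of which 1810 are 0 in every library, and every column matched 1 sample title.

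Total estimated counts per library ranged from 17925890 to 26791776, which limits the precision for genes of few CPM. For gene positions, 19176 symbols were matched to the GENCODE v29 annotation of GRCh38, 436 of them through a newer symbol. Symbols are printed as in the deposited table. Of 490 genes in the fixed lists, 6 stand in the table under an older symbol and 0 were missing. The 66 genes of the Y chromosome, including its pseudoautosomal part, were left out of tests.

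The estimated counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3 (trimmed mean of M values factors, low counts removed with the default expression filter, quasi-likelihood F test). The design had a term for the medium and an additive term for title series, the 3 runs of sample title numbers. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Fold changes are NASH against LGLI, from the fit, and standard errors were taken as the absolute log2 fold change divided by the square root of F. CPM, counts scaled to a common library size, use the normalization factors and are given as mean ± SD, also where one medium differs between title series. A separate fit with a mean for each medium and series gave the log2 fold changes within each series and the test of whether they differ. Gene lists with at least 5 tested members were tested two-sided against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 25 lists. camera was repeated with an estimated correlation, and fry was run as well. Library totals were compared with an exact permutation test (SciPy 1.17.1). Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9 were used for tables and plots.

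The design, the 27 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM in one medium and the same sign in all 3 series, up to 4 members of each list with the smallest p, and 19 genes chosen for their role in liver metabolism. Not every gene the rule takes is given in the text. PDGFRA, PDGFRB, SOX9 and the single exceptions named to a list's direction were chosen after their values were seen, unless the rule also takes them. Replicates are numbered within each medium and a number does not pair samples. Replicates within a medium and series were compared by a chi-square over genes, and no pair agreed within sampling noise (6.39 to 125 per gene, the highest values in pairs with LGLI replicate 6).

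Alternatives were other normalization factors (RLE, upper quartile), no filter and a stricter filter on low counts (at least 50 counts in 8 libraries), limma voom, DESeq2 1.42.0, no term for title series, a log2 fold change of at least 1, leaving out each library, each title series or the 2 libraries whose titles lack a D number, and leaving out mitochondrially encoded genes and the 20 most abundant genes before scaling. The mean of the within-series differences, thinning to the smallest library total, the correlation estimated within series and medium, and the interaction without the most abundant genes were added after seeing the data. The tests were checked on simulated counts with known changes. For the media difference 34%, 66%, 87.8% and 100% of genes changed by 1.25, 1.5, 2 and 4-fold were recovered (13297 genes run), and 8 of 150 calls were unchanged genes. For a difference between title series 0%, 4%, 50% and 77.6% were recovered at the same sizes (13266 genes run), and 3 of 68 calls were unchanged genes. In the list test, a single simulated draw with 25 lists, the 1 shifted list was called and no other list was. This does not show how often lists are called falsely where their members move together. The correlations estimated in the data ranged from −0.00222 (gluconeogenesis list) to 0.939 (mitochondrially encoded proteins). Each gene check changed 200 genes, against 6982 called in the data, so its rates may not hold for the data. The simulated media change was the same in every series, whereas in the data it differed between series for 21.5% of tested genes. The check of a difference between series placed the change in series 3 alone.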

Results

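RNA of human hepatocytes, the main cell type of the liver, was measured in 17 libraries from cell pellets collected at day 10 of culture. Cells in 9 libraries had been kept in LGLI medium, the control medium with low glucose and low insulin, and cells in 8 libraries in NASH medium. NASH stands for non-alcoholic steatohepatitis, a liver disease with fat accumulation and inflammation. The composition of the NASH medium is not given in the sources used here. Sample titles fall into 3 runs of numbers, called title series 1, 2 and 3 here, each with both media: 3 LGLI and 3 NASH libraries in series 1 and in series 2, and 3 LGLI and 2 NASH libraries in series 3. The labels do not say what the runs stand for. Within each run the LGLI titles carry the lower numbers and the NASH titles the higher. The D numbers, where a title has one, follow the same order within each run, and the labels do not say what they stand for. An effect of either order cannot be told apart from the medium. Nothing in the labels says that libraries of one medium came from separate cultures or donors, so p-values measure only the spread between these samples. Total estimated counts per library ranged from 17925890 to 26791776. The NASH libraries held 21487822 ± 3037742 counts (SD, n = 8) and the LGLI libraries 19625064 ± 2224557 (SD, n = 9). This difference of 1862758 counts was within the spread between libraries (exact two-sided permutation test, p = 0.168). Within the series the NASH mean exceeded the LGLI mean by 1674127 counts (series 1, exact p = 0.2), 183950 counts (series 2, exact p = 1) and 4842775 counts (series 3, exact p = 0.4). With 20, 20 and 10 arrangements these exact tests cannot go below 0.1.

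The comparison asks what the NASH medium changes in these cells, as part of building a culture system of this disease from human liver cells. Of 13484 genes tested, 3516 were higher and 3466 lower in NASH medium, together 51.8% (edgeR quasi-likelihood test with a term for title series, Benjamini-Hochberg adjusted p below 0.05). At least 2-fold changes were fewer, 876 higher and 457 lower. The same sign was found in all 3 title series for 92.8% of the called genes. Calling them from these same series favours this. The first principal component of log2 CPM (counts scaled to a common library size) held 36.2% of the variance and placed every LGLI library below 0 and every NASH library above 0. The second component, with 21.5%, set title series 1 apart from series 2 and 3. The 20 most abundant genes took 32.9% to 39.1% of the counts in LGLI libraries and 26.2% to 30.1% in NASH libraries.

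**Figure D1:**
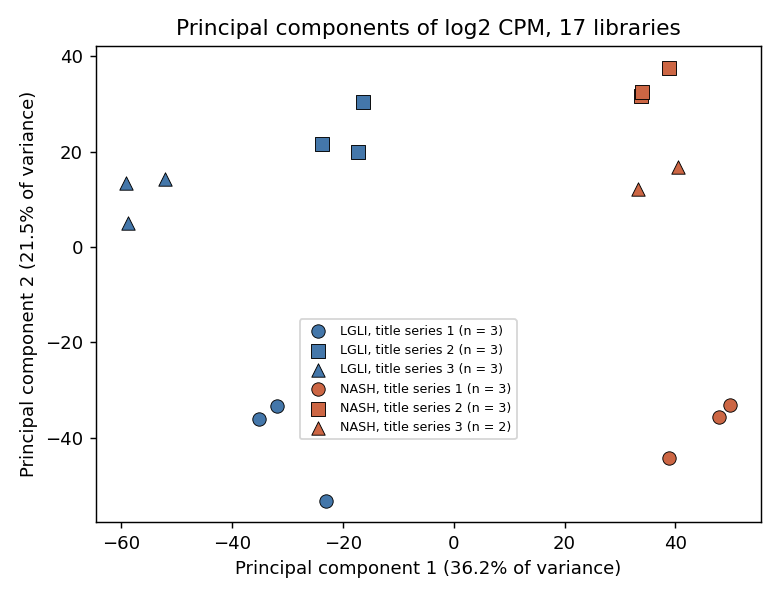
Each point is 1 library, placed by its first (horizontal, 36.2% of variance) and second (vertical, 21.5%) principal component of log2 CPM, in arbitrary units; colour gives the medium and shape the title series. The LGLI libraries lie to the left of 0 and the NASH libraries to the right, and title series 1 lies below the other series.

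Among genes with at least 5 CPM in one medium and the same sign in all 3 series, the 8 largest rises were in ANGPTL2 (38.9-fold), MYO7B (28.8-fold), SLC10A1 (26.5-fold), CYP4A22 (25.4-fold), HR (24.4-fold), INHBB (23.6-fold), APOA4 (19.6-fold) and EPO (19.2-fold). ANGPTL2, MYO7B, HR and INHBB averaged 0.230, 0.223, 0.511 and 0.334 CPM in LGLI medium, so their fold changes rest on very low values. SLC10A1 encodes NTCP, the main transporter that takes bile salts from blood into hepatocytes. It went from 3.41 ± 4.04 CPM (SD, n = 9) to 72.0 ± 26.7 CPM (SD, n = 8), a log2 fold change of 4.73 (SE 0.31, edgeR adjusted p = 3.69e-09). APOA4, an apolipoprotein of triglyceride-rich particles, went from 2.94 ± 2.51 to 51.7 ± 38.8 CPM (log2 fold change 4.29, SE 0.28, edgeR adjusted p = 2.34e-09). EPO encodes erythropoietin, the hormone of red blood cell formation. The 8 largest falls were in FGF12 (21.4-fold), PLA2G2A (20.6-fold), ARG2 (13.5-fold), LCN2 (13.1-fold), SLC37A2 (11.8-fold), S100P (9.04-fold), MKX (8.56-fold) and SPINK1 (7.96-fold). LCN2, a secreted iron-siderophore binding protein of the acute phase, fell from 26.5 ± 24.0 to 1.51 ± 0.758 CPM (log2 fold change −3.71, SE 0.22, edgeR adjusted p = 1.44e-09). SPINK1, a secreted trypsin inhibitor, fell from 1079 ± 222 to 141 ± 84.6 CPM. For 12 of these 16 genes all 8 NASH libraries lay beyond all 9 LGLI libraries, which the choice of the largest changes favours. FGF12, PLA2G2A, SLC37A2 and S100P were the exceptions. SLC37A2, which averaged only 0.361 CPM in NASH medium, was not called in series 2 (log2 fold change −0.62, edgeR adjusted p = 0.456). On GRCh38, in the GENCODE v29 annotation, SLC10A1 spans chromosome 14 from 69775417 to 69797289, APOA4 chromosome 11 from 116820700 to 116823306, EPO chromosome 7 from 100720800 to 100723700, LCN2 chromosome 9 from 128149071 to 128153455 and SPINK1 chromosome 5 from 147824568 to 147831786. All are protein-coding, and a value covers all transcripts of a gene.

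Genes of fatty acid and triglyceride synthesis rose: 13 of 20 members were higher and 1, ACACA, was lower, and the counts adjusted over the list alone were the same (camera adjusted p = 0.00185 with a preset correlation, adjusted p = 0.478 with an estimated correlation). FASN, the fatty acid synthase on chromosome 17 (82078333 to 82098332), rose 5.36-fold from 271 ± 138 CPM (SD, n = 9) to 1420 ± 583 CPM (SD, n = 8), with a log2 fold change of 2.42 (SE 0.27, edgeR adjusted p = 1.11e-06). SCD, the desaturase that makes monounsaturated fatty acids (chromosome 10, 100347124 to 100364834), rose 4.57-fold to 6920 ± 3484 CPM (edgeR adjusted p = 0.000237), with log2 fold changes of 2.03, 0.68 and 4.17 in series 1, 2 and 3. PNPLA3, a lipid droplet protein with a common liver disease variant, rose 2.14-fold. SREBF1, a transcription factor of lipid synthesis, rose 1.66-fold over all libraries, with log2 fold changes of 1.26, −0.30 and 1.31 in the 3 series, and its call was lost without series 1 (edgeR adjusted p = 0.228) or without series 3 (0.136). ACACA, the cytosolic acetyl-CoA carboxylase, had a log2 fold change of −0.26 and lost its call without series 2 (edgeR adjusted p = 0.351) and without a term for title series (0.321). In cholesterol synthesis and uptake 9 of 25 members were higher and 1, HSD17B7, was lower, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.162, adjusted p = 0.855 with an estimated correlation), except without series 1 (camera adjusted p = 0.0331) or series 2 (0.0198). The call of HSD17B7 was lost without series 2 (edgeR adjusted p = 0.0526) and without a term for title series (0.182). Its member HMGCS1, an early enzyme of sterol synthesis, rose 1.40-fold. This call was lost without series 3 (edgeR adjusted p = 0.173) and without a term for title series (0.208), and the list median was 0.86 in series 3 against −0.08 and −0.09 in series 1 and 2.

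Fatty acid oxidation and ketogenesis genes were higher in NASH medium for 12 of 20 members and lower for HADH (12 and 2 adjusted over the list alone; camera adjusted p = 0.00148, adjusted p = 0.439 with an estimated correlation). HADH had log2 fold changes of −0.99, −0.71 and 0.39 in the 3 series, called in each, and its call over all libraries was lost without series 1 (edgeR adjusted p = 0.361) or series 2 (0.212). CYP4A11, a fatty acid omega-hydroxylase, rose 17.1-fold from 5.12 ± 2.11 to 88.1 ± 24.2 CPM, and its near-identical neighbour CYP4A22 rose as well. Reads shared by this pair can be assigned to either gene, so their separate values are uncertain. ACADVL, the first enzyme of mitochondrial oxidation of very long chains, rose 2.56-fold from 155 ± 18.8 to 394 ± 86.3 CPM (log2 fold change 1.36, SE 0.08, edgeR adjusted p = 1.46e-09). CPT1A, which controls fatty acid entry into mitochondria, rose 1.41-fold, and lost its call without a term for title series (edgeR adjusted p = 0.153) and without series 2 (0.06). In series 3 it was not called (edgeR adjusted p = 0.971, interaction adjusted p = 0.00229). The list median was −0.15 in series 1, 0.49 in series 2 and 0.88 in series 3. Of the lipid droplet and fatty acid handling genes 11 of 21 were higher, while PLIN4 and FITM1 were lower, also adjusted over the list alone. This list was not called (camera adjusted p = 0.0543, adjusted p = 0.478 with an estimated correlation). It was called higher without a filter on low counts (camera adjusted p = 0.0262), with the stricter filter (0.0132), without series 1 (0.0204) or series 2 (0.0385) and without some single libraries. PLIN2, the main droplet coat protein of hepatocytes (chromosome 9, 19108375 to 19149290), rose 3.82-fold from 137 ± 46.1 to 544 ± 229 CPM (edgeR adjusted p = 4.89e-07). ANGPTL4, an inhibitor of lipoprotein lipase, rose 5.77-fold and G0S2, an inhibitor of triglyceride breakdown, 4.66-fold. PDK4, which restrains pyruvate oxidation, had log2 fold changes of −0.24, 0.81 and 1.03 in the 3 series and 0.52 over all libraries (edgeR adjusted p = 0.0279), a call lost without series 2 (0.277) or series 3 (0.241) and without a term for title series (0.178). Lipoprotein assembly and transport genes rose: 15 of 19 were higher and 1, ABCA1, was lower, with the same counts adjusted over the list alone (camera adjusted p = 5.27e-05, adjusted p = 0.276 with an estimated correlation). APOA2, a structural protein of high-density lipoprotein, rose 7.62-fold from 226 ± 66.5 to 1782 ± 708 CPM, and APOA5, which promotes triglyceride clearance, rose 5.54-fold.

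**Figure D2:**
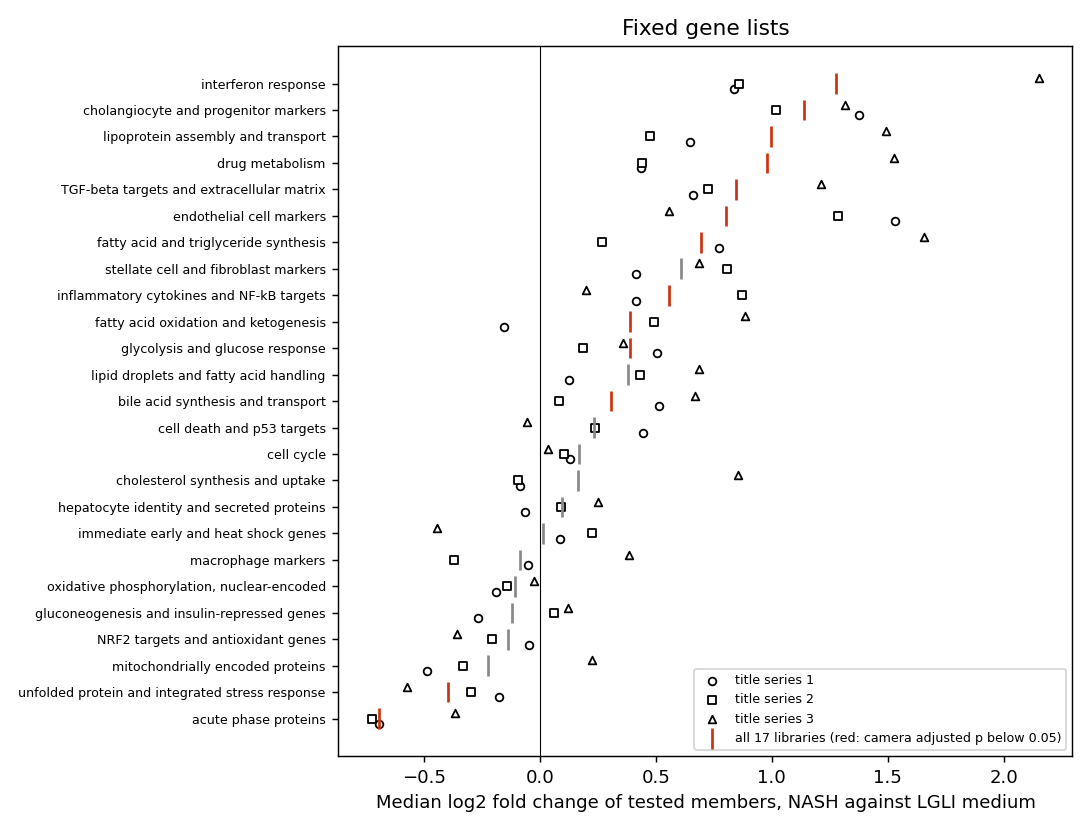
Horizontal axis, median log2 fold change (NASH against LGLI medium) of the tested members of each of the 25 tested gene lists; vertical bars are over all 17 libraries (red, camera adjusted p below 0.05 with the preset correlation) and open symbols are medians within title series 1, 2 and 3. Of these, the interferon response list has the highest median, 1.28, and acute phase proteins the lowest, −0.70.

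Among glycolysis and glucose response genes 13 of 21 were higher and HK1, PFKFB3, PGK1 and ENO1 were lower (13 and 5 adjusted over the list alone; camera adjusted p = 0.0224, adjusted p = 0.276 with an estimated correlation). The list was not called without series 1 (camera adjusted p = 0.0616). TXNIP, a glucose-induced regulator of glucose uptake, rose 5.46-fold from 27.7 ± 7.66 to 147 ± 37.8 CPM, and PKLR, the liver pyruvate kinase, rose 4.83-fold from 39.8 ± 16.2 to 190 ± 56.3 CPM. PFKFB3, PGK1 and ENO1, all in glycolysis or its control, fell by 0.62, 0.26 and 0.52 on the log2 scale. The call of HK1 was lost in 6 of the fits without 1 library, without series 1 (edgeR adjusted p = 0.0596) or series 3 (0.312) and without a term for title series (0.0701). Gluconeogenesis and insulin-repressed genes moved both ways, with 6 of 14 higher and 7 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.922, adjusted p = 0.95 with an estimated correlation). Their median was −0.12 and their mean 0.04, the sign of the camera test. PCK1, which catalyses the first committed step of gluconeogenesis, rose 6.25-fold, and G6PC, the glucose-6-phosphatase, 2.67-fold. The log2 fold change of G6PC was 2.96 in series 1 and was not called in series 2 (0.69, edgeR adjusted p = 0.0598) or series 3 (0.49, 0.182). IGFBP1, an insulin-repressed secreted protein, fell 2.32-fold and PPARGC1A, a coactivator of the fasting response, 2.75-fold. IGFBP1 was not called in series 1 (log2 fold change −0.36, edgeR adjusted p = 0.366).

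Bile acid synthesis and transport genes were higher for 12 of 21 members and lower for CYP7B1, ABCB11 and NR1H4, also adjusted over the list alone (camera adjusted p = 0.0183, adjusted p = 0.276 with an estimated correlation). The list call was lost without series 3 (camera adjusted p = 0.0582) and with the stricter filter on low counts (0.0524). The lower calls of CYP7B1 and ABCB11 were lost as well, without series 1 (edgeR adjusted p = 0.129) or series 3 (0.337) for CYP7B1 and without series 2 (0.0529) for ABCB11. Besides SLC10A1, the basolateral exporter subunit SLC51A rose 9.90-fold from 9.18 ± 6.07 to 84.3 ± 21.4 CPM. CYP7A1, the rate-limiting enzyme of bile acid synthesis (chromosome 8, 58490178 to 58500236), was at 22.2 ± 25.7 CPM in LGLI and 13.8 ± 12.7 CPM in NASH medium. Its log2 fold change of −0.71 (SE 0.70) was not called over all libraries (edgeR adjusted p = 0.419), but the values of −3.00, −1.78 and 2.72 in the 3 series were each called, in opposite directions. Drug metabolism genes were higher for 13 of 22 members and lower for CYP1A1 and UGT2B4, also adjusted over the list alone (camera adjusted p = 0.00911, adjusted p = 0.392 with an estimated correlation). CYP3A4, the most used drug-metabolising enzyme of the liver, rose 6.10-fold from 153 ± 136 to 708 ± 506 CPM, with log2 fold changes of 3.70, 0.29 and 3.71 in the 3 series. GSTA1 rose 3.10-fold, although reads shared with its close paralog GSTA2 make its own value uncertain. CYP1A1 and UGT2B4 fell 2.15-fold and 1.58-fold, CYP1A1 without a call in series 1 (edgeR adjusted p = 0.14).

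Hepatocyte identity and secreted protein genes moved both ways, with 8 of 22 higher and 6 lower, also adjusted over the list alone (camera adjusted p = 0.922, adjusted p = 0.961 with an estimated correlation). ALB, serum albumin, was at 30520 ± 6228 CPM in LGLI and 39770 ± 14002 CPM in NASH medium, a difference not called over all libraries (log2 fold change 0.36, SE 0.20, edgeR adjusted p = 0.156). Within the series it was called in opposite directions, −0.65 in series 1 and at least 0.79 in series 2 and 3 (edgeR interaction adjusted p = 3.22e-05). It was called without series 1 (log2 fold change 0.89, edgeR adjusted p = 5.26e-05) and as the mean of the within-series differences (0.38, edgeR adjusted p = 0.000595). TF, transferrin, rose 7.25-fold from 1190 ± 551 to 7986 ± 743 CPM (edgeR adjusted p = 2.08e-08). FGA, a fibrinogen chain that is also induced in the acute phase (chromosome 4, 154583126 to 154590766), fell 3.72-fold from 28706 ± 7266 to 8416 ± 4376 CPM (edgeR adjusted p = 1.01e-06). Both FGA and ALB count among very abundant transcripts, and the share of the 20 most abundant genes was lower in NASH medium, as given above. Acute phase proteins fell: 10 of 18 were lower and CP, CFB and SAA4 were higher (11 and 3 adjusted over the list alone; camera adjusted p = 0.0213, adjusted p = 0.392 with an estimated correlation). Without series 1 this list was not called (camera adjusted p = 0.0504). SERPINA3 fell 2.27-fold from 12685 ± 2753 to 5688 ± 2193 CPM, and SOCS3, a feedback inhibitor of cytokine signalling, fell 4.25-fold. CP, the copper carrier ceruloplasmin, rose 2.22-fold from 2128 ± 434 to 4682 ± 352 CPM.

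**Figure D3:**
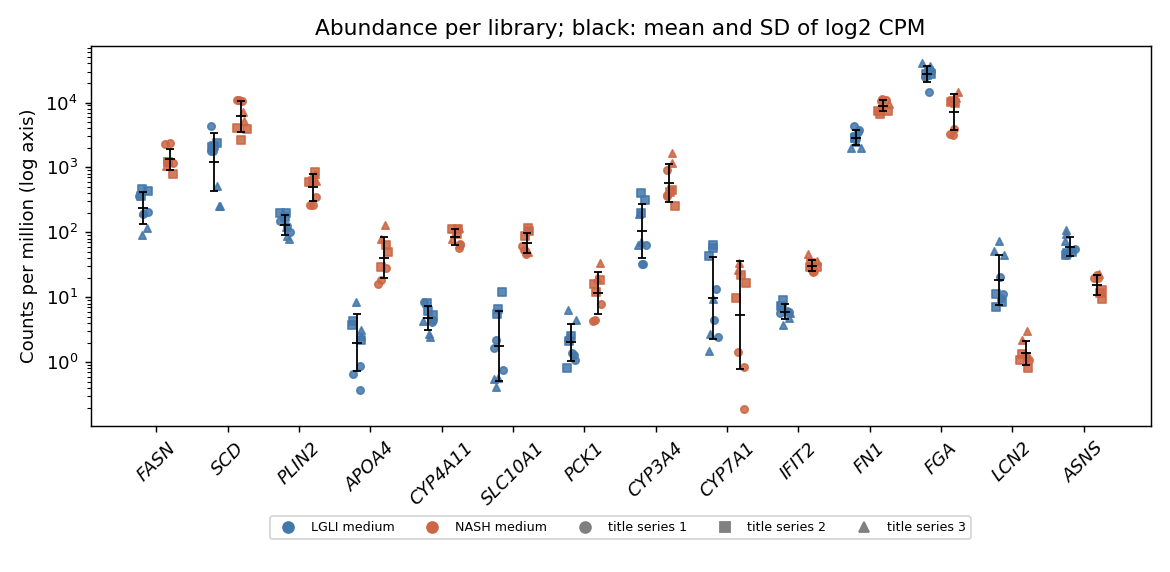
CPM of 14 genes (vertical log axis), 1 point per library, coloured by medium and shaped by title series; black bars are the mean ± SD of log2 CPM over 9 LGLI or 8 NASH libraries. All NASH libraries lie above all LGLI libraries for FASN, PLIN2, APOA4, CYP4A11, SLC10A1, IFIT2 and FN1 and below them for FGA, LCN2 and ASNS, while the media overlap for SCD, PCK1, CYP3A4 and CYP7A1.

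Interferon response genes rose: 17 of 19 were higher and none was lower (18 and 0 adjusted over the list alone; camera adjusted p = 5.39e-07, adjusted p = 0.276 with an estimated correlation). IFIT2, which binds viral RNA, rose 5.10-fold from 6.19 ± 1.54 to 31.5 ± 7.26 CPM, and OAS2, a sensor of double-stranded RNA, rose 3.09-fold. Of the inflammatory cytokines and NF-kB targets 10 of 15 were higher and 1, CXCL2, was lower, also adjusted over the list alone (camera adjusted p = 0.0128, adjusted p = 0.276 with an estimated correlation). This call was lost without series 2 (camera adjusted p = 0.0878). CXCL8, a chemokine that attracts neutrophils, rose 2.48-fold from 16.3 ± 8.36 to 37.0 ± 19.9 CPM, while CXCL2, another neutrophil chemokine, fell 4.35-fold from 51.1 ± 10.4 CPM. TGF-beta targets and extracellular matrix genes rose: 18 of 24 were higher and 1, SPP1, was lower, also adjusted over the list alone (camera adjusted p = 5.27e-05, adjusted p = 0.276 with an estimated correlation). FN1, the matrix protein fibronectin, rose 3.05-fold from 2979 ± 818 to 9115 ± 1741 CPM (edgeR adjusted p = 7.04e-09). COL1A1, a chain of type I collagen, rose 2.45-fold from 18.5 ± 12.9 to 42.0 ± 18.9 CPM. TGFB1 itself had a low abundance, 1.11 ± 0.771 and 1.42 ± 0.799 CPM, and its difference was not called (edgeR adjusted p = 0.461). SPP1, secreted osteopontin, fell 4.15-fold.

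Unfolded protein and integrated stress response genes fell: 14 of 19 were lower and 2, CALR and PPP1R15A, were higher, also adjusted over the list alone (camera adjusted p = 0.00134, adjusted p = 0.276 with an estimated correlation). The call of CALR was lost without series 1 (edgeR adjusted p = 0.138). DDIT3, the stress-induced transcription factor CHOP, fell 2.80-fold from 49.0 ± 9.62 to 17.6 ± 2.69 CPM, and ASNS, asparagine synthetase, fell 3.71-fold from 63.6 ± 24.0 to 16.2 ± 5.51 CPM. FGF21, a hormone induced by fasting and stress, was at 31.1 ± 20.7 and 28.3 ± 4.69 CPM and was not called (edgeR adjusted p = 0.943). NRF2 targets and antioxidant genes were not called as a list, with 5 of 20 higher and 8 lower, also adjusted over the list alone (camera adjusted p = 0.0971, adjusted p = 0.489 with an estimated correlation). It was called lower without series 1 (camera adjusted p = 0.0349). SLC7A11, the cystine importer, fell 4.28-fold. Cell death and p53 targets were not called, with 8 of 16 higher and 1, BCL2L11, lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.0948, adjusted p = 0.276 with an estimated correlation), and CDKN1A, the cell cycle inhibitor p21, rose 2.06-fold. The list was called without series 3 (camera adjusted p = 0.025), and the call of BCL2L11 was lost without series 2 (edgeR adjusted p = 0.0647). In the cell cycle list 2 of 15 genes, CCND1 and TYMS, were higher and AURKA was lower (2 and 0 adjusted over the list alone; camera adjusted p = 0.552, adjusted p = 0.597 with an estimated correlation). CCND1, cyclin D1, rose 3.79-fold, and the call of TYMS was lost without series 2 (edgeR adjusted p = 0.175). The call of AURKA was lost in 10 of the fits without 1 library, without series 1 (edgeR adjusted p = 0.211) or series 3 (0.46) and in thinned libraries (0.0524). Immediate early and heat shock genes moved both ways, with 6 of 15 higher and 7 lower (7 and 7 adjusted over the list alone; camera adjusted p = 0.919, adjusted p = 0.95 with an estimated correlation). Their median was 0.01 and their mean −0.04, the sign of the camera test. JUN rose 2.82-fold and HSPA1A, an inducible chaperone nearly identical to HSPA1B and so of uncertain separate value, fell 2.77-fold.

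Nuclear-encoded oxidative phosphorylation genes were lower for 10 of 21 members and higher for 3, among them NDUFA9 and SDHA, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0543, adjusted p = 0.522 with an estimated correlation). It was called lower without a filter (camera adjusted p = 0.042), without series 3 (0.025) and without some single libraries (0.0249 to 0.0493). The call of NDUFA9 was lost in 9 of the fits without 1 library, without series 1 (edgeR adjusted p = 0.123) or series 2 (0.129), without a term for title series (0.197), with upper quartile factors (0.0567) and without a filter (0.0506), and that of SDHA in 3 of them, without series 2 (edgeR adjusted p = 0.0948) and without series 3 (0.272). NDUFA4, a small subunit of the respiratory chain, fell 1.58-fold from 165 ± 18.9 to 103 ± 12.8 CPM (edgeR adjusted p = 3.94e-08). Of the 13 mitochondrially encoded proteins MT-ND3 and MT-ND4L were lower and none higher (0 and 0 adjusted over the list alone; camera adjusted p = 0.333, adjusted p = 0.884 with an estimated correlation). LGLI replicate 6 held 15.4% of its counts in these genes, against 5.64% to 8.80% in the other LGLI libraries. Without it the log2 fold change of MT-ND4L went from −0.45 to −0.21 and was not called (edgeR adjusted p = 0.0578). The call of MT-ND4L was lost in 10 of the 17 fits without 1 library, with limma voom (adjusted p = 0.0619), without a term for title series (0.0845) and without series 1 (0.0704) or series 2 (0.186), and that of MT-ND3 in 2 of the 17 fits and without series 1 (0.172) or series 2 (0.177).

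Markers of other liver cell types were measured as well. Cholangiocyte and progenitor markers rose: 8 of 10 were higher and none lower (9 and 0 adjusted over the list alone; camera adjusted p = 0.00145, adjusted p = 0.199 with an estimated correlation). KRT19, a keratin of bile duct cells, rose 2.89-fold from 2.26 ± 0.822 to 6.22 ± 2.45 CPM and CD24 3.53-fold, while SOX9, named after its values were seen, was at 3.33 ± 1.21 and 3.50 ± 1.64 CPM and was not called (edgeR adjusted p = 0.822). Endothelial markers were higher for 4 of 8 members, TIE1, KDR, FCN3 and PECAM1, and lower for none, also adjusted over the list alone (camera adjusted p = 0.0348, adjusted p = 0.276 with an estimated correlation). Their levels were low, with TIE1 at 0.269 ± 0.279 and 3.28 ± 0.688 CPM, and the list call was lost without series 1 (camera adjusted p = 0.0872) and without a term for title series (0.108). Stellate cell and fibroblast markers were higher for 9 of 13 members, among them TAGLN (1.90-fold) and COL1A1, which the matrix list also holds. The receptors PDGFRA and PDGFRB, named after their values were seen, were lower, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.0543, adjusted p = 0.335 with an estimated correlation). The list was called higher without series 1 (camera adjusted p = 0.0331), without the 2 libraries lacking a D number (0.042) and without some single libraries. The call of PDGFRA was lost in 6 of the fits without 1 library, without series 3 (edgeR adjusted p = 0.3), without a term for title series (0.463) and with limma voom (adjusted p = 0.0514). Of 8 macrophage markers CD68 was higher (3.95-fold) and MRC1, CD14 and FCER1G were lower, also adjusted over the list alone (camera adjusted p = 0.868, adjusted p = 0.888 with an estimated correlation). The call of CD14 was lost in 11 of the fits without 1 library, without series 2 (edgeR adjusted p = 0.457) or series 3 (0.191), without a term for title series (0.146) and also with RLE factors (0.054), without a filter (0.0604), without the most abundant genes (0.0574) and with limma voom (0.0531), and that of FCER1G without series 3 (edgeR adjusted p = 0.132). Of the lymphocyte markers 1, KLRD1, was tested and was lower (log2 fold change −0.76, edgeR adjusted p = 0.00914), a call lost without series 3 (0.0618). NASH replicate 3 stood apart with 1.28 CPM of KLRD1, against 3.17 to 6.09 in the other NASH libraries. No red blood cell marker was abundant enough to test.

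Over the 25 lists tested, camera with the preset correlation of 0.01 called 11 lists higher and 2 lower. With the correlation estimated for each list it called 0, with 4 lists at an unadjusted p below 0.05, and fry, which tests a list's own direction and not against other genes, called 16 higher and 4 lower. No list called with the preset correlation was called with the estimated one.

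The media difference itself differed between title series for 2897 genes, 21.5% of those tested (edgeR test of the interaction, adjusted p below 0.05), and 318 of them were called in opposite directions in different series. CYP7A1 had the widest range over the series among the genes named, 5.72 on the log2 scale (edgeR interaction adjusted p = 0.000463). SCD, CYP3A4 and PLA2G2A were changed least in series 2, with ranges of 3.49, 3.42 and 4.77. Tested within each series, 2652 genes were higher and 2800 lower in series 1, 2050 and 1744 in series 2, and 3214 and 2945 in series 3. Log2 fold changes correlated across genes with Pearson's r of 0.634 (series 1 and 2), 0.627 (series 1 and 3) and 0.640 (series 2 and 3), genes not being independent replicates. Of the genes called from 2 series, 90.4%, 91.6% and 89.3% had the same direction in the remaining series 1, 2 and 3, and 49.98%, 52.98% and 61.86% were also called in that direction in that series alone.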

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

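The tests in this part of depth, of a single deviating library and of the most abundant genes were all set before their results were seen, though thinning and leaving out the most abundant genes were added as alternatives after the data had been seen.

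The difference between media differed between title series for 2897 of 13484 genes by the edgeR interaction test, and for 53 of the 104 genes named in the text. Their log2 fold changes differed between the lowest and the highest series by 5.72 for CYP7A1, 4.77 for PLA2G2A, 4.34 for SLC37A2, 3.73 for ANGPTL2, 3.49 for SCD, 3.42 for CYP3A4, 3.23 for TIE1, 3.04 for EPO, 3.03 for SLC10A1, 2.62 for HR, 2.48 for G6PC and 2.03 for G0S2. The range was 1.93 for ARG2, 1.86 for SLC51A, 1.86 for TF, 1.70 for FGF21, 1.68 for PLIN2, 1.68 for FASN, 1.66 for SLC7A11, 1.66 for PKLR, 1.65 for ALB, 1.62 for AURKA, 1.61 for SREBF1, 1.49 for CYP4A11, 1.45 for CYP1A1, 1.40 for IGFBP1, 1.39 for PLIN4, 1.39 for TXNIP, 1.38 for HADH, 1.38 for TYMS, 1.36 for FGA, 1.35 for HSPA1A, 1.34 for APOA2, 1.34 for PPARGC1A, 1.27 for PDK4, 1.18 for IFIT2, 1.16 for MT-ND3, 1.11 for ASNS, 1.11 for HMGCS1, 1.11 for SPINK1, 1.08 for CFB, 1.08 for CXCL2 and 1.04 for PNPLA3. It was below 1 for CCND1 (0.94), CPT1A (0.87), OAS2 (0.81), GSTA1 (0.80), FN1 (0.80), CYP7B1 (0.65), ENO1 (0.62), CDKN1A (0.59), CALR (0.57) and ABCA1 (0.45).

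A difference in depth does not account for the whole of this, since 2760 genes still differed between series after every library was thinned to the smallest total. A single library does not either: the count stayed between 2036 (without NASH replicate 7, which leaves 1 NASH library in series 3, assumed to vary like the others) and 3909 (without LGLI replicate 6), above 1448.5, which is 50% of the count over all libraries. Leaving out the most abundant and the mitochondrially encoded genes before scaling gave 2899 genes. What the title series stand for stays open, since the labels do not say it: a processing batch and a difference in the origin of the cells cannot be told apart here, and neither was tested. The interaction test measures series differences against the spread between libraries of one medium and series. Nothing in the labels shows these to be separate cultures, so variation between cultures could also enter the count.

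In 12 of 264 groups of libraries 1 library stood apart from the rest by Dixon's test, where chance gives about 1 in 20, and 8 of the 12 were LGLI replicate 6. Its mitochondrially encoded share was 15.4% (others 5.64% to 8.80%) and the mean log2 CPM of that list 13.17 (others 11.57 to 12.25). It also had 4592 CPM of MT-ND4L (others 1358 to 1864), 388 of APOA2 (others 177 to 258), 77.6 of CXCL2 (others 43.7 to 52.6), 14778 of FGA (others at least 24558), 74.6 of ABCB11 (others at least 108) and 1.98 of FCN3 (others at most 0.264). NASH replicate 8 had 592 CPM of ACADVL (others 336 to 438) and 12.5 of DDIT3 (others 16.5 to 20.9). NASH replicate 3 had 1.28 CPM of KLRD1 (others 3.17 to 6.09), and LGLI replicate 9 had 12.3 of PDGFRB (others 21.3 to 37.2).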

How the results depend on the processing

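The mean of within-series differences, the thinned libraries and the correlation estimated within series and medium were chosen after seeing the data. Higher and lower gene counts stayed within 1.5 times of the reported ones in every alternative but one: requiring a log2 fold change of at least 1 left 876 and 457 by construction. The other counts ranged from 2713 (no term for title series, that is no replicate block, with 2747 lower) to 3898 higher, and from 2696 (without title series 3) to 3909 lower. The genes differing between series numbered 2036 to 3909. Without the block, 5449 of 6982 calls were shared in direction. That threshold also ends 35 of the 99 calls of named genes. Apart from it, 78 of 104 named genes kept direction and call in every alternative that tested them (8 were not tested with the stricter filter, 6 without the most abundant genes, 2 without the block and 1 without title series 1), and in at least 1 alternative 22 lost the call (ABCB11, ACACA, AURKA, BCL2L11, CALR, CD14, CPT1A, CYP7B1, FCER1G, HADH, HK1, HMGCS1, HSD17B7, KLRD1, MT-ND3, MT-ND4L, NDUFA9, PDGFRA, PDK4, SDHA, SREBF1, TYMS), and ALB and CYP7A1 gained one (CYP7A1 without title series 3, −2.15). Leaving out 1 library ended the calls of ACACA (NASH 8, edgeR adjusted p = 0.0511), MT-ND3 (NASH 4 and 6, up to 0.0571), CYP7B1 (LGLI 4, NASH 7 and 8, up to 0.0652), SDHA (LGLI 8, NASH 7 and 8, up to 0.0756), PDK4 (LGLI 1 and 3, NASH 1 and 8, up to 0.0844), HK1 (LGLI 1, 5 and 9, NASH 2, 7 and 8, up to 0.0871), PDGFRA (LGLI 1 and 4, NASH 3, 6, 7 and 8, up to 0.0816), and of NDUFA9, AURKA, MT-ND4L and CD14 in 9, 10, 10 and 11 of 17 fits (up to 0.0745, 0.116, 0.0897 and 0.107). It added list calls for lipid droplets (without LGLI 1, LGLI 6, NASH 4 or NASH 6, 0.0421 to 0.0472), stellate markers (without LGLI 1, NASH 4, 6 or 7, 0.041 to 0.05) and oxidative phosphorylation (without LGLI 2, 4 or 8, NASH 6, 7 or 8, 0.0249 to 0.0493). Other list calls added by camera were lipid droplets (no filter 0.0262, stricter filter 0.0132, without title series 1 0.0204 or 2 0.0385, without the 2 libraries lacking a D number 0.0468), oxidative phosphorylation (no filter 0.042, without title series 3 0.025), stellate markers (without title series 1 0.0331, without the 2 libraries 0.042), cholesterol (without title series 1 0.0331 or 2 0.0198), NRF2 targets (without title series 1 0.0349) and cell death (without title series 3 0.025). Changes of sign were found in uncalled genes: CYP7A1 (0.16 without title series 1, 0.15 without 2), FGF21 (−0.14 without the block, −0.10 without title series 1, −0.30 without 3, −0.16 to 0.15 over the 17 fits without 1 library, 6 of them reversed) and SOX9 (0.069 without the block, 0.096 without title series 1, −0.090 to 0.030 over the 17, 2 reversed). Without the 2 libraries lacking a D number the calls of ACACA, PDK4, MT-ND3, MT-ND4L, PDGFRA, NDUFA9 and CD14 were lost (edgeR adjusted p = 0.0609 to 0.131). camera called 0 higher and 0 lower lists with either estimated correlation, 4 and 5 lists having an unadjusted p below 0.05, and fry called 16 higher and 4 lower. Lists called higher by fry alone or newly were lipid droplets (fry adjusted p = 0.00026), gluconeogenesis (0.0294), cell death (1.16e-05), cell cycle (0.00165) and stellate markers (0.000112). Newly lower by fry were NRF2 targets (fry adjusted p = 0.000498) and oxidative phosphorylation (0.00116). Lists not called changed sign with these adjusted p: cholesterol 0.392 without title series 3; gluconeogenesis 0.974 without the block, 0.982 without title series 2 and 0.904 without 3; hepatocyte identity 0.985 without title series 2, 0.866 without 3, 0.727 by fry and without LGLI 9 or NASH 7 (0.866 to 0.999 over all 17 fits without 1 library, most of which kept the sign); immediate early genes 0.95 without the block, 0.737 without title series 3 and without NASH 7 (0.804 to 0.965 over all 17); macrophage markers 0.912 with the stricter filter, 0.974 without the block, 0.96 without title series 2 and 0.776 by fry. The library total difference stayed within the spread, at 2111461, 2770289 and 929039 counts without title series 1, 2 and 3 (exact p = 0.26, 0.121 and 0.489). Apart from the log2 threshold the causes were not tested.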

Other observations

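The tests of cell type markers in this part were chosen after the result was seen. The length test and the counts over other splits were set before.

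The median log2 fold change of interferon response genes was 0.84 in series 1, 0.86 in series 2 and 2.15 in series 3, and that of drug metabolism genes 0.44, 0.44 and 1.52. Fatty acid and triglyceride synthesis genes had medians of 0.77, 0.27 and 1.66, and lipoprotein genes 0.65, 0.48 and 1.49. These medians were not tested against each other. Of the members tested, 15 of 19 interferon genes, 18 of 22 drug metabolism genes, 13 of 20 fatty acid and triglyceride synthesis genes and 15 of 19 lipoprotein genes differed between series by the edgeR interaction test. Lists were not compared with each other. Among the 2897 genes that differed between series, 61.1% had series means that lay farther apart in LGLI than in NASH medium, against 51.5% of the other tested genes. This comparison of shares was not tested.

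In NASH medium 8 of 10 cholangiocyte markers, 4 of 8 endothelial markers and 9 of 13 stellate cell and fibroblast markers were higher, though none of these lists was called with an estimated correlation (adjusted p = 0.199, 0.276 and 0.335). This could come from a different mix of cells in the pellets or from changed expression in hepatocytes. A lower share of hepatocytes would raise the markers of every other cell type alike if the mix of the others stayed the same. The cholangiocyte list median lay 1.223 above the macrophage list median on the log2 scale (95% bootstrap interval over genes 0.43 to 2.15). This cannot decide the question, since the interval does not measure the spread between libraries and only 8 of 16 macrophage markers were tested. These did not move together, with 1 called higher and 3 lower, so a lower share of hepatocytes stays open. More cholangiocytes would raise all their markers, and SOX9 lay 8.77 of its standard errors below the list median, with a log2 fold change of −0.04, while KRT19 and CD24 rose. SOX9 is 1 gene of low abundance, below 5 CPM in both media, so more cholangiocytes cannot be excluded. More stellate cells or fibroblasts stay open as an explanation: 2 tested markers, PDGFRA and PDGFRB, were lower, but 1 of them, PDGFRB, stayed called lower whichever 1 library was left out (highest edgeR adjusted p = 0.00328), while PDGFRA was not (highest 0.0816, and 0.3 without title series 3). Changed expression within hepatocytes stays open too and was not tested.

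Short length is a possible source of bias for the 10 nuclear-encoded oxidative phosphorylation genes that were lower in NASH medium. Their median exon length was 2468 bases against 5134 over all tested genes. Exon length here is the union of all annotated exons of a gene and not the length of the transcripts expressed. By this measure of length, bias as the whole cause is argued against. In limma 10 of the 10 kept an adjusted p below 0.05 after a smooth length trend was removed from each library. Their median log2 fold change was −0.32 before and −0.38 after. Over 13332 genes Spearman's rho of exon length and log2 fold change was −0.019. An effect of the medium on these genes stays a hypothesis.

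Chance in how libraries fall into groups was examined with 99 drawn splits of the 17 libraries into 9 and 8, and the real one as the 100th. The draws were not kept within title series. No drawn split gave as many higher genes (3516, highest other 294, 1 of 100 splits as large) or lower genes (3466, highest other 241, 1 of 100). Drawn splits mixed libraries of both media in each group, so the media difference widened the spread within groups and could keep their counts low. They also take libraries as independent, which the labels do not show. These splits therefore do not exclude chance. For higher lists 3 of 100 splits gave as many as the real 11, but 5 of 100 reached 11 lists in one direction when either direction was counted, so chance is not clearly excluded. The highest other also had 11, in 2 splits with 5 and 6 real NASH libraries among the 8, where edgeR called 0 genes higher and 0 lower. The count of lists holds only at the preset correlation, as camera called 0 lists with either estimated one (4 and 5 lists at an unadjusted p below 0.05, 16 higher and 4 lower by fry). For lower lists these splits cannot exclude chance, since 51 of 100 gave at least the real 2 and the highest other gave 11. In the 12 splits with 8 or more lower lists 1 to 3 of the 8 were real NASH libraries. Among the 13 splits with 8 or more higher lists 4 to 6 were. The direction of the lists thus went with the mix of real NASH libraries. These splits therefore carry the media difference and do not give list counts under chance alone.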
